A study of Mus musculus with 8 samples.

How the data were processed

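The series measured N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, in colonic epithelial cells of C57BL/6 mice at postnatal week 6. RNA was enriched with an m6A antibody, so that methylated stretches appear as peaks of reads over the unenriched RNA (the input). The 8 samples fall into 4 groups by genotype and RNA fraction. They are 3 m6A immunoprecipitates and 1 input from control mice with floxed Mettl14 alleles, and 3 immunoprecipitates and 1 input from mice that also carry the CDX-cre transgene, in which Mettl14 is deleted. Mettl14 is a subunit of the methyltransferase complex that writes m6A. Per the labels' protocols, libraries were built with a strand-preserving kit for small amounts of RNA, from 5 ug of total RNA. Nothing in the labels says whether the replicates came from separate animals, and the sex of the mice is not given there.

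A single processed file was used, the authors' deposited table of peaks that passed their test for a difference between the genotypes. It has 1 value per peak and no column of any sample, so the number of reads, the depth of each library and the spread between replicates are unknown, and no error or replicate test can be given for a peak. All 195 peaks have a false discovery rate (FDR) for the genotype difference of about 0.05 or less; peaks that did not pass are not analysed here. Per the submitters' processing notes, the reads were handled with Trim Galore 0.6.5, HISAT2 2.1.0, HOMER 4.10.0 and R 3.6 on mouse build mm10, with no role given for each tool. The peak caller is not given in the sources used here; per the file headers, the columns and their spelling are those written by the R package exomePeak. The fold enrichment of a peak is a linear ratio of immunoprecipitate over input, as deposited by the authors. The deposited score of a peak is its p-value for that enrichment, and the next columns hold the log10 of the same p-value and of its FDR; log10 of the score and the log10 p-value column differed by at most 0.02. The genotype difference was deposited as the log10 of a p-value and of an FDR, which were turned back into linear values here, and as a log2 fold change. How the authors combined the 3 immunoprecipitates and the single input of each genotype is not given in the sources used here.

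The table does not say which genotype is the numerator of the log2 fold change. In exomePeak the fold change is the treated arm over the untreated arm, and the design text names the deletion of Mettl14 as the manipulation. A positive value therefore likely means more m6A in the knockout and a negative value less, but the sign is reported as deposited, and peaks are called positive or negative. With 1 input per genotype, and the way it entered the value not given, a change in m6A and a change in the amount of RNA were not separated here.

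Gene names were taken from the table and matched to the RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes. Of 168 distinct names, 164 were current symbols in that table, 4 matched as older names and 0 stayed unmatched. Of the 195 peaks, 193 lay wholly inside the RefSeq span of their gene and 2 reached past it. Coordinates are 1-based on mm10. The RefSeq table gives gene spans without exons or sequence, so the planned assignment of peaks to untranslated and coding regions and the planned search for the m6A consensus motif were not run. In their place, chosen after seeing the data, the peak's exon blocks as deposited and the position of its midpoint along the gene span, counted from the 5' end on the peak's strand, were used.

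Computation was in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Peaks of different sign were compared by permuting the sign across peaks (100000 permutations, two-sided, smallest p 1e-05) or by Fisher's exact test. Correlations across peaks have permutation p-values. Intervals of shares are exact Clopper-Pearson intervals at 95%, and intervals of medians are exact binomial intervals of the order statistics. These tests and intervals treat listed peaks as units; peaks are not biological replicates and peaks of 1 gene are not independent, so the tests describe the list. The permutation functions were tested on 100 simulated sets of 195 peaks each: 3 sets passed 0.05 for a width that did not differ and 100 for one that did, and 2 and 100 sets for an absent and a present correlation. The simulated peaks were independent and their width difference was larger than that in the list, so these counts do not give the power of the tests below. Shares of peaks and permutation within bins were not simulated.

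Before the data were examined, 19 gene lists with 529 distinct genes, the alternatives and the rule for named genes were fixed. The rule names the 12 genes with the most negative and the 8 with the most positive peak (leaving out genes listed under a clone or predicted name), the 5 peaks with the smallest p-value, every list member with a listed peak, genes with 3 or more peaks or with peaks of both signs, and Mettl14, Mettl3 and Nfkbia. No enrichment test was run on the lists, because the peaks that were tested but did not pass are not part of the table. The alternatives were a stricter FDR of 0.01, a minimum absolute log2 fold change of 1 or 2, 1 peak per gene, merging of overlapping peaks, and peaks with at least the median enrichment. One item of the table is not reported here by name and was left out of a gene list written after the table was seen.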

Results

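N6-methyladenosine was mapped by antibody enrichment in colonic epithelial cells of mice with floxed Mettl14 (control) and of floxed mice with CDX-cre (Mettl14 knockout), with 3 immunoprecipitates and 1 input library per genotype. The comparison asks which m6A sites in this tissue differ when a core subunit of the m6A writer is deleted. Every position, fold enrichment, log2 fold change and FDR below is the authors' own value from the authors' deposited table of differential peaks, which holds 195 peaks on 168 genes. Of these genes, 162 are protein-coding, 5 are long noncoding RNAs and 1 is an antisense RNA. Depth per library is unknown and no replicate error can be attached to a peak. The sign of a log2 fold change is given as deposited, and positive likely means knockout over control. Were it control over knockout, the direction of every value below would turn, and the larger group of peaks, here positive, would be the one lower in the knockout.

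The listed differences in m6A signal went both ways, with 120 positive peaks on 109 genes and 75 negative peaks on 59 genes. They do not separate a change in m6A from a change in the amount of RNA, so a positive value need not mean more methylation. Nor do they measure the total m6A of either genotype, so the share of positive peaks does not show whether total m6A rose. The largest positive values belonged to the transcription factor gene Spib, the chemokine gene Ccl20 and the secreted glycoprotein gene Lrg1, and the largest negative ones to the prolactin receptor gene Prlr, the fructose transporter gene Slc2a5 and the galactosyltransferase gene Ugt8a. Positive peaks made up 61.5% of the list (95% exact interval 54.3 to 68.4%, which covers counting error only). The median log2 fold change was 1.36 among positive peaks (95% interval of the median 1.12 to 1.55, a 2.58-fold difference) and -1.46 among negative peaks (-1.63 to -1.23, a 2.75-fold difference). An absolute log2 fold change of at least 1 left 76 positive and 63 negative peaks, 54.7% positive, with an exact interval (46.0 to 63.1%) that includes an even split. The balance depended on the build of the peak: among the 93 peaks with 1 exon block only 32.3% were positive, and among the 102 peaks spread over more blocks 88.2% were.

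**Figure D1:**
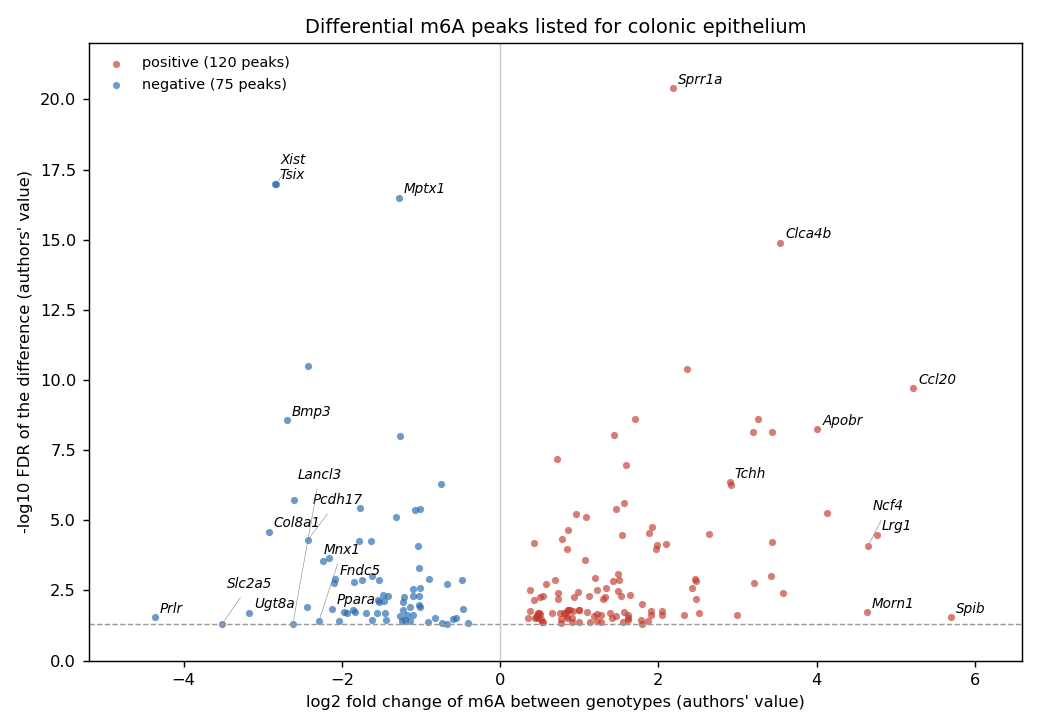
Each point is 1 of the 195 peaks of the authors' deposited table, with its log2 fold change between genotypes on the x axis and -log10 of its FDR on the y axis. The dashed line marks an FDR of 0.05, and labels sit at the peak with the smallest p-value of each gene named by size or p-value. Sprr1a is the highest point at 2.18, and Xist and Tsix lie together near -2.8.

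The most positive peak in the authors' deposited table lay in Spib, an Ets-family transcription factor of B cells and intestinal M cells, at a log2 fold change of 5.70 (FDR 0.029, chromosome 7, 44529540 to 44532071, minus strand, 4 exon blocks). The authors' log10 p-value for the enrichment of this peak was -5.15, against -3.19 for the weakest peak of the list. By that p-value it was one of the weaker peaks, with 211 nt of exon blocks. Ccl20, the chemokine ligand of the receptor CCR6, followed at 5.22 (FDR 1.9e-10). Its peak had 4 exon blocks at chromosome 1, 83116766 to 83119167, and spanned 100% of the gene. Lrg1, a secreted leucine-rich glycoprotein of the acute phase, was at 4.76 (FDR 3.2e-05) and had the highest enrichment over input in the list, 152-fold. The other genes among the 8 most positive were Ncf4, a subunit of the phagocyte NADPH oxidase, at 4.65, Morn1 at 4.63, Tchh, a structural protein of the hair follicle, at 4.13, Apobr, a lipoprotein receptor, at 4.01, and Clca4b, of the family of chloride channel accessory proteins, at 3.54. The smallest FDR of the list, 4.0e-21, belonged to Sprr1a, a small proline-rich protein of the cornified envelope, with a log2 fold change of 2.18 over a peak spanning 100% of the gene (chromosome 3, 92483954 to 92485881).

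On the negative side of the authors' deposited table, the prolactin receptor gene Prlr was lowest at -4.36 (FDR 0.028, chromosome 15, 10333029 to 10333179, plus strand, 1 exon block). Its peak was a weak one, 151 nt wide and enriched 2.77-fold. The authors' log10 p-value for its enrichment was -3.75, against -3.19 for the weakest peak of the list. The fructose transporter gene Slc2a5 stood at -3.51 (FDR 0.048) and Ugt8a, which makes galactosylceramide, at -3.17 (FDR 0.019). Col8a1, a chain of type VIII collagen, had 3 negative peaks between -2.92 and -1.46, and Bmp3, of the bone morphogenetic protein family, had 2, at -2.69 and -1.01. Xist, the noncoding RNA that silences one X chromosome in female cells, had 3 peaks between -2.83 and -2.43, the first with an FDR of 1.0e-17. A peak assigned to its antisense partner Tsix overlapped that Xist peak over 98.3% of the shorter peak and had nearly the same value, -2.85. Whether both rest on the same reads was not settled, and both are counted among the 75 negative peaks; without the peaks that overlap a listed peak on the opposite strand, 117 positive and 73 negative peaks were left. Further genes among the 12 lowest that the rule names were Lancl3 at -2.62, Fndc5, the irisin precursor, at -2.44, Pcdh17, a protocadherin, at -2.43, Mnx1, a homeobox factor, at -2.29, and Ppara, the nuclear receptor of fatty acid oxidation, at -2.13. The rule left out Gm6086 at -2.24, which RefSeq names Gal3st2c. Mptx1, a mucosal pentraxin, had a smaller difference, -1.28, with one of the 5 smallest p-values (FDR 3.2e-17).

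The epithelial cell type genes with a listed peak were of both signs. Without the peaks that did not pass, whether their number is small or large cannot be judged. Of 18 goblet cell genes 3 had a listed peak: Mptx1 and Ang4, an antimicrobial ribonuclease at -1.32 (FDR 7.4e-06), were negative, and the membrane mucin gene Muc13 was positive at 0.35 (FDR 0.03), the smallest positive value of the list. Of 29 absorptive colonocyte genes only Guca2b, which encodes uroguanylin, was listed, at 1.44 (FDR 9.1e-09). Of 20 enteroendocrine and tuft cell genes only Chga, the secretory granule protein chromogranin A, was listed, at -0.49 (FDR 0.0013). The 25 proliferation genes gave Mki67 alone, at -0.41 (FDR 0.047). Of 35 genes of lipid and nutrient transport, Ppara and Slc12a2, the basolateral sodium-potassium-chloride cotransporter, were listed, and both were negative (Slc12a2 at -1.08, FDR 4.3e-06).

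Signalling lists had at most 1 listed gene each, and every one of these was positive in the authors' deposited table. Since 64.9% of all listed genes were positive, this uniform sign in so few genes is not a result about signalling. It also depends on list membership, as Bmp3, negative at -2.69, was not on the TGF-beta, BMP and Hippo list. Of 35 NF-kB pathway genes, Nfkb2, a subunit of the transcription factor itself, was at 2.1 (FDR 6.8e-05). Of 37 genes of TNF receptor signalling and cell death, the pro-apoptotic gene Bax was at 0.92 (FDR 0.018). The interferon and innate sensing list (31 genes) gave Socs3, a feedback inhibitor of cytokine receptors, at 1.32 (FDR 0.0054). Bmp4 from the TGF-beta, BMP and Hippo list (27 genes) was at 1.27 (FDR 0.024), and Areg, an EGF receptor ligand, from the growth factor list (35 genes) was at 1.0 (FDR 0.044). Among markers of other cell types, 1 of 21 stromal, endothelial, muscle and neural genes was listed, the collagen gene Col1a1 at 1.61 (FDR 0.035), and 0 of 22 immune cell genes were. Of 30 macrophage and monocyte genes chosen after the table was seen, 9 were listed, none of them on that immune cell list. No member was listed from the m6A machinery (24 genes), Wnt and stem cell (32), Notch and secretory fate (18), junction and barrier (28), unfolded protein response (18), chromatin regulator (39) and immediate early (36) lists. A gene missing from the table either did not pass the authors' test or had no peak tested, and these cases cannot be separated here. In all, 14 of the 529 list genes had a listed peak, 8 positive and 6 negative. With so few members, no list was tested for a shift.

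Mettl14 itself (chromosome 3, 123368295 to 123385990), its partner Mettl3 and the NF-kB inhibitor gene Nfkbia had 0 listed peaks, so the table offers no check of the knockout through the targeted transcript. The listed peak nearest to Mettl14 was that of Ugt8a, 2.53 Mb away. Chromosome 3 carried 17 peaks, more than any other chromosome, on 12 genes. That is 7.14% of the listed genes (95% exact interval 3.75 to 12.1%), against 4.49% of RefSeq protein-coding genes (exact binomial test, two-sided, p = 0.13, adjusted p = 0.63 over 21 chromosomes).

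Genes with several peaks were uniform in sign. Of the 22 genes with over 1 listed peak, 9 had only positive and 13 only negative peaks, and 0 had both. Clca4b had the most, with 4 peaks between 3.21 and 3.54 spread over its gene on chromosome 3. Sstr1, a somatostatin receptor gene, had 3 peaks between -1.97 and -1.10, as many as Col8a1 and Xist.

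Positive and negative peaks differed in their layout along the gene span, which includes introns. Negative peaks such as those of Prlr, Slc2a5 and Pcdh17 were mostly single blocks late in the gene span, while positive peaks such as those of Spib, Ccl20 and Ncf4 were mostly spread over several exons. Of the 120 positive peaks, 75% had over 1 exon block (95% exact interval 66.3 to 82.4%), against 16% of the 75 negative peaks (8.55 to 26.3%; Fisher's exact test, two-sided, p = 2.2e-16, adjusted p = 6.6e-16 over 9 such shares). In all, 70 positive peaks and 1 negative peak had 3 or more blocks. The median midpoint lay at 91.7% of the gene span from the 5' end for negative peaks and at 46.7% for positive peaks (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1.7e-05 over 5 comparisons of this kind). In 3 equal bins of gene span, the negative and positive medians were 52.6% and 48.2% in the shortest genes, where only 7 peaks were negative, 83.2% and 39.1% in the middle bin, and 94.8% and 69.3% in the longest genes. Among peaks with 1 block this difference was small, with medians of 94.1% and 90.9% (permutation p = 0.31). Spliced width did not pass the test, with medians of 523 nt for positive and 450 nt for negative peaks (permutation p = 0.24, adjusted p = 0.24), nor did enrichment over input, with medians of 4.88-fold and 4.01-fold (permutation p = 0.13, adjusted p = 0.16). The genes carrying positive peaks were shorter, with a median span of 8353 nt against 31189 nt (permutation p = 1e-05, adjusted p = 1.7e-05). A different measure is the distance in nucleotides from the end of the peak, not its midpoint. By it, 39.2% of positive peaks (95% exact interval 30.4 to 48.5%) and 22.7% of negative peaks (13.8 to 33.8%) ended within 1000 nt of the 3' end of the gene (Fisher's exact test, two-sided, p = 0.019, adjusted p = 0.024 over the 9 shares). A peak that covers a short gene, such as that of Ccl20, counts as near the 3' end by this measure. So do positive peaks of 1 block such as that of Bmp4, which spans 15% of its gene. Why the midpoint and the distance rank the signs differently was not tested.

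**Figure D2:**
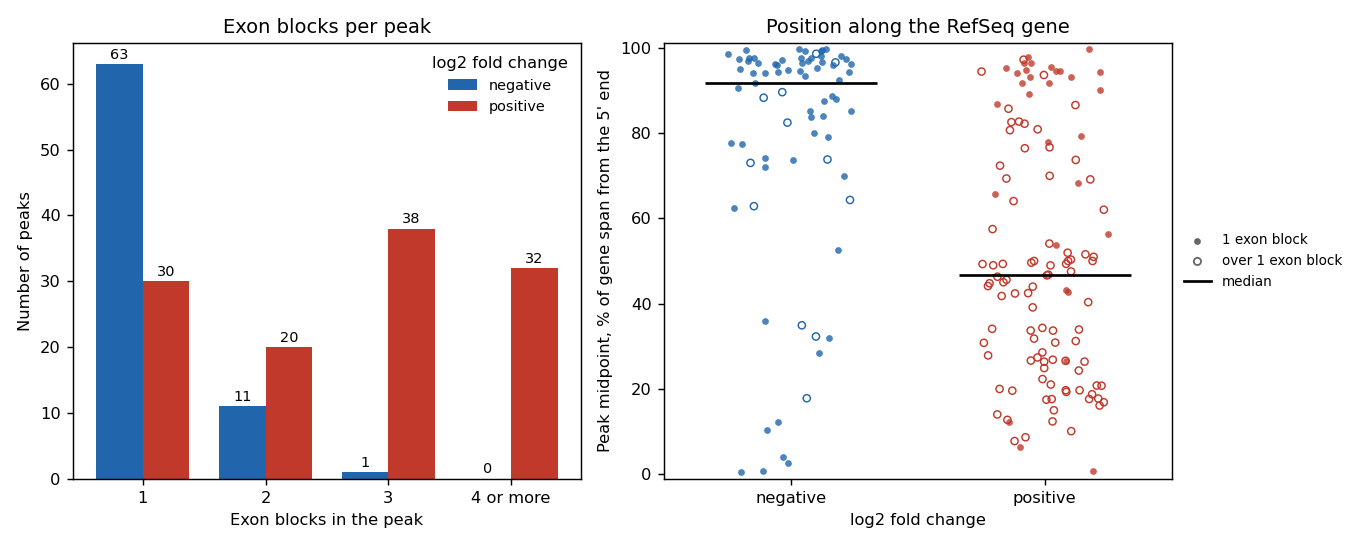
Left, number of peaks by how many exon blocks they have, for negative (blue) and positive (red) log2 fold changes; bars start at 0. Right, the midpoint of each peak as a percent of its RefSeq gene span from the 5' end, with filled points for 1 block, open points for more, and lines at the medians of 91.7% and 46.7%; 32 positive and 0 negative peaks have 4 or more blocks.

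Enrichment over input and size of change were related among positive peaks, with exceptions. Of the 7 most enriched peaks, all positive, Lrg1, Tchh, Apobr and Morn1 had log2 fold changes above 4 at 152, 97.4, 68.8 and 62.6-fold enrichment. The others, named after their values were seen, were Igfbp5 at 2.64 (143-fold), Tnfaip8l2 at 1.78 (74.2-fold) and Tmem119 at 1.62 (81.7-fold), and the most positive peak, in Spib, was enriched 5.96-fold. Across the 120 positive peaks, enrichment and the size of the log2 fold change had a Pearson r of 0.48 and a Spearman rho of 0.54 (permutation p = 1e-05 for each, adjusted p = 1.5e-05 over 3 relations). Without the 2 peaks farthest from the median enrichment, r was 0.46. Across the 75 negative peaks, r was 0.03 (permutation p = 0.77) and rho was -0.06 (permutation p = 0.60); the difference between the signs was not tested. Pooled over all 195 peaks, r was 0.42 and rho 0.34 (permutation p = 1e-05 for each), and r was 0.38 without the 2 farthest peaks. These are correlations across peaks, which are not independent replicates. Only peaks that passed the authors' test of the difference are listed, and this selection can by itself relate peak strength to size of change. Both values also draw on the same immunoprecipitates, so the p-values describe the list only. The sign of the relation turned when the -log10 p-value of the peak replaced its fold enrichment (rho -0.30 for positive peaks, permutation p = 0.0011).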

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

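The stricter FDR of 0.01 left 64 positive and 40 negative peaks and 7 of the 14 list genes, a minimum absolute log2 fold change of 1 left 76 positive and 63 negative peaks, and a minimum of 2 left 30 positive and 19 negative peaks; fewer peaks pass by construction. The intervals of the positive share at these minima, 46.0 to 63.1% and 46.2 to 74.8%, include an even split, so a positive majority was not resolved there. Among peaks with at least the median enrichment there were 68 positive and 31 negative peaks (68.7% positive) and the positive median was 1.79. Chosen after seeing the data, peaks with 1 block reversed the balance, with 30 positive peaks or 32.3%, and peaks with more blocks raised it to 88.2%, with 12 negative peaks; the cause was not tested. The relation of peak strength to size of change reversed with the -log10 p-value of the peak in place of its enrichment (rho -0.38 for all, -0.30 for positive peaks), and negative peaks then passed the test, at -0.55. With spliced width, added after seeing the data, rho was -0.27 for all and -0.59 for negative peaks, and positive peaks showed no relation that passed (-0.10, permutation p = 0.26). The cause was not tested. Genomic span in place of spliced width gave a difference in medians of 2074 nt that passed, since it includes the introns between blocks. The difference in position was -3.2% of gene span among peaks with 1 block and no longer passed. Of the other values, 29 planned and 12 added ones, and all 35 values of named genes, kept their direction, and those with a test their side of its threshold. Part of this was fixed beforehand. With 0 genes having peaks of both signs, no named gene could change direction. A log2 scale cannot change a rank correlation, and permuting within bins leaves the observed difference as it was, so only its p-value could move. No 2 listed peaks overlapped on 1 strand, so merging changed nothing. No paired analysis was possible because the table holds no value of a sample; for the same reason leaving out a replicate was not run, and transcript regions and motifs were not run for want of exon annotation and sequence. Depth limits cannot be stated, as read counts are unknown.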

Other observations

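All tests in this part were chosen after the table was seen. Those on strand sharing, on sex and on macrophage RNA were chosen after their own result was seen too. The tests of the 5 gene lists also used genes picked with their signs in view. Gene groups written with the table in view had uniform signs. Of 30 macrophage and monocyte genes, 9 were listed and all 9 were positive, with a median log2 fold change of 2.36. Of the 30, 5 were also on a list fixed in advance, and 0 of these 5 were listed. The immune cell list fixed in advance had 0 of 22 genes listed. The 9 listed macrophage genes included the 3 chains of complement C1q, C1qc at 2.47, C1qb at 2.36 and C1qa at 1.92, the pore-forming protein gene Mpeg1 at 2.42 and the chemokine receptor gene Ccr1 at 2.99. Of 35 genes of regenerating or fetal-like epithelium, 10 were listed and all 10 were positive, among them Slpi, a secreted protease inhibitor, at 3.43, Clu, which encodes clusterin, at 2.92, and Anxa8 at 1.53. Of 28 genes of the epithelial inflammatory response, 9 were listed and all 9 were positive, among them the antimicrobial lectin gene Reg3g at 1.98 and Ubd, a ubiquitin-like modifier, at 1.71; Slpi is on both of these lists. Of 26 actin and actomyosin genes, 8 were listed and all 8 were positive, with smaller values from Capg at 1.43 to Tmsb4x at 0.45.

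The PPAR-alpha and gluconeogenesis list went the other way: of 23 genes 4 were listed and all 4 were negative, namely Ppara at -2.13, Apob at -1.26, the coactivator gene Ppargc1a at -1.24 and the gluconeogenic enzyme gene Pck1 at -1.23. Against the other listed genes, Fisher's exact test (two-sided) of the sign gave p = 0.014 for this list, 0.015 for regenerating epithelium, 0.028 for macrophages and for inflammation, and 0.052 for actin. Adjusted over the 5 lists these were 0.035 for each of the first 4 and 0.052 for actin. The lists were written with the table in view, so these values are not independent evidence.

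The layout of peaks, with positive peaks over several exons and negative peaks in 1 block, is the pattern that most invites a closer look. The tables argue against shorter genes as the whole cause: within 3 equal bins of gene span, positive peaks had over 1 block more often by at least 51.2 percentage points, a bin with only 7 negative peaks, and by at least 66.3 in the others. Wider peaks were argued against as the whole cause in the same way, with a smallest difference of 37.4 points within bins of spliced width (stratified permutation p = 1e-05 for both). Of the 7 negative peaks in the bin of shortest genes, 3 lay in Sstr1. The number of exons in each gene was not known, so its part in the layout was not tested. Single peaks over a whole gene do not account for most of it, since 18 of the 90 positive peaks with several blocks, or 20%, spanned 80% or more of their gene (95% exact interval 12.3 to 29.7%). Such a span still differed by sign, with 19 of 120 positive and 0 of 75 negative peaks (Fisher's exact test, two-sided, p = 7.9e-05, adjusted p = 0.00012 over the 9 shares). Each peak was scored alone, so coverage of a gene by several peaks together stays open. A change in RNA amount against the single input and a change in where m6A sits both stay open, as untested; no biological explanation was tested.

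The Tsix and Xist peaks may be 1 set of reads counted on both strands: they overlap over 98.3% of the shorter peak and their log2 fold changes differ by 0.02, although the library kit preserves strand. Plet1os also overlaps both Plet1 peaks on the opposite strand, by 185 and 22 nt of exon blocks. For the negative Xist values, a different sex makeup of the arms cannot be told apart from the genotype, because the labels give no sex and 0 peaks on the Y chromosome were listed, which decides nothing in a list of differential m6A peaks.

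For the macrophage genes, a candidate explanation is that RNA from macrophages differs between the arms, which the table cannot settle: 100% of the listed members were positive, yet the members had been seen before the list was written. The abundant macrophage genes Lyz2, Cd68 and Csf1r had no listed peak, which excludes nothing, and expression values are not analysed here.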
